A study of Homo sapiens with 6 samples.

How the data were processed

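RNA immunoprecipitation followed by sequencing (RIP-seq) was measured in HepG2, a human hepatocellular carcinoma cell line. Per the labels, 6 libraries were made: 2 with an antibody against PABPC1 from cells overexpressing PABPC1, 2 with an antibody against PABPC4 from cells overexpressing PABPC4, and 1 rabbit IgG control from each of these cell populations. Per the labels' protocols, lysate was incubated with antibody on protein A/G magnetic beads, RNA was extracted from the beads, and libraries were built with a SMART-seq type kit primed with random primers. Whether reads were counted by strand is not given in the sources used here. Nothing in the labels says that the replicates came from separate cultures, so p-values from them measure only the spread between these libraries, which may be technical.

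The authors deposited 2 tables of their own comparisons, each with 58302 genes, a fold, a p-value and an adjusted p for PABPC1 against IgG and PABPC4 against IgG; 0 columns held values of single libraries. Per the file headers, the fold is a linear ratio of RIP over IgG and the adjusted p is a Benjamini-Hochberg value. The submitters' processing notes name Bowtie2 2.4.1, STAR 2.7.10a, featureCounts 2.0.1 and the builds GRCh38 and hg38, without saying which step each served. How the authors computed their p-value was worked out from the deposited values: it equals a chi-square test with Yates' correction on the reads summed over libraries against the rest of each total, with a largest log ratio of recomputed to deposited p of 9.7e-14. Such a p-value covers counting error only and leaves out the spread between libraries. The deposited fold equals the mean depth-scaled value of the RIP libraries over that of the IgG libraries, with 0.005 RPKM added to the IgG mean, so that a gene with no IgG read has a very large listed fold.

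Because the deposited p-values and folds take a limited set of values, whole reads could be recovered from them. Summed reads came out for 17561 of the 17565 genes with a deposited p in the PABPC1 table and for 21450 of 21455 in the PABPC4 table. The totals were 566769 reads for PABPC1, 1691517 for PABPC4 and 227265 for IgG, with the RIP totals within 0.0012 of a whole number. In 21005 of 21005 genes solved in each table separately, both tables gave the same IgG reads, so both comparisons used the same pooled IgG libraries, although the labels assign 1 IgG library to each cell population. The folds then split the sums into libraries for 15010 of 15010 genes with reads in both RIPs. In all, 15091 genes have reads for each of the 6 libraries, and 7511 of the 22604 genes with a read have summed reads only. As a check, the gene length implied by the deposited fold was a whole number of nucleotides, within 0.001, in 15091 of 15091 genes. With the IgG totals shifted by 1 read this held in 0 of 10899 genes. Reads were not recovered for LIN9, MUC16, CACNA1A and the mitochondrial rRNA genes MT-RNR1 and MT-RNR2. The mitochondrial rRNA reads were taken as what the other genes leave of each total.

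The recovery does not tell which library is replicate 1 or 2, nor which IgG library belongs to which cell population. Libraries are therefore called A and B within each antibody. Their totals were 289217 and 277552 reads for PABPC1, 850190 and 841327 for PABPC4, and 133030 and 94235 for IgG. These are low depths for whole transcriptomes, and the IgG libraries limit the precision of both comparisons against IgG. Ratios carry exact 95% intervals from the summed reads, and shares carry exact (Clopper-Pearson) 95% intervals. These intervals cover counting error only. A gene with 0 reads on 1 side has a bound computed against a floor of 3 reads over the group, which leaves out counting error, and an exact limit beside it. On simulated tables of known reads, the recovery returned 20627 of 20627 sums and 15432 of 15438 sets of library reads.

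The designs, the gene lists, the rule for named genes and the alternatives to be tried were fixed before the data were examined. The planned main test was a negative binomial model for read counts, with the authors' values described without a test if the tables held only folds and p-values. The tables did, so the comparisons with IgG are the deposited calls at an adjusted p under 0.05, and the difference between the enrichments is the median log2 ratio of the deposited folds over genes with at least 20 PABPC1 reads. The comparison of PABPC4 RIP with PABPC1 RIP was fitted after the recovery with limma 3.58.1 (voom) in R 4.3.3, a choice made after seeing the data. It used 7976 genes with at least 10 reads in at least 2 libraries, 3 groups (PABPC1, PABPC4, IgG), median-of-ratios scaling, 3 residual degrees of freedom and empirical Bayes moderation with 34.9 prior degrees of freedom. The pooled IgG cancels from the fold of PABPC4 over PABPC1, but this fit is centred on the median gene while the difference between the enrichments keeps the library totals. The IgG libraries still enter through the filter, the scaling and the spread. Adjusted p-values are from limma with Benjamini-Hochberg adjustment, or deposited where so named. On simulated reads, limma called 98.2% of 4-fold changes between the RIPs at a dispersion of 0.001 and 93.6% at 0.02. For PABPC4 against IgG the shares were 79.2% and 68.4%. These limma shares cover only the changed genes that passed its filter, 168 and 171 of 200 at the 2 dispersions. The chi-square test called 76% of 4-fold and 13% of 2-fold changes in the simulated PABPC1 comparison, and 83% and 17% in the PABPC4 comparison. None of these shares was computed by read depth, so they do not give the power for genes with few reads.

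A set of 29 gene lists, with 893 different genes, covered RNA classes with and without a poly(A) tail, liver, growth and stress programs, partners of poly(A)-binding proteins, and markers of other cell types. Lists with at least 5 tested genes were tested with camera (limma, preset correlation 0.01, repeated with an estimated correlation), and each member was counted both at the adjusted p over all genes and adjusted over the list alone. Of the 29 lists, 23 could be tested. Named genes are MYC, PABPC1 and PABPC4; the 8 largest and 6 smallest folds past the threshold with at least 5 CPM and both duplicates on the same side; and, for each list, the called member with the largest fold in each direction, or the one with the smallest p where none passed. Further examples with the most reads in a list, the mitochondrial rRNA genes, LYZ, IGF2, SEC14L1 and members of the gene families tested in the closing section were chosen after their values were seen. RNA classes were assigned from the RefSeq table of GRCh38.p14, which matched 17758 symbols (78.6%). Counts and tables were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.

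Alternatives recomputed the calls with other library totals (without mitochondrial rRNA, over nuclear-encoded genes, median-of-ratios), other thresholds and filters, Fisher's exact test, limma in place of the chi-square test, each library left out in turn, and PABPC4 reads thinned to the PABPC1 depth in 100 draws. Where leaving out a library left 1 library on a side, the lone library was assumed to vary like the others. Genes with near-identical copies (7SL RNA genes, HBA1 and HBA2, SRGAP2D, nuclear copies of mitochondrial rRNA) and antisense genes can share reads with their partners, so their values are uncertain.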

Results

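The series measured which RNAs came down with 2 cytoplasmic poly(A)-binding proteins in HepG2 hepatocellular carcinoma cells, and its title places PABPC4 in liver cancer driven by MYC. PABPC1 is the abundant member of the family, which coats the poly(A) tail of mRNA, and PABPC4 is a less abundant relative. Duplicate immunoprecipitations of each protein, from cells that per the labels overexpress it, were set against rabbit IgG immunoprecipitations. The PABPC1 libraries held 289217 and 277552 recovered reads, the PABPC4 libraries 850190 and 841327, and the IgG libraries 133030 and 94235.

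The RIPs held more mRNA and less mitochondrial rRNA than the IgG controls. Protein-coding mRNA made up 37.1% of IgG reads (exact 95% interval 36.9% to 37.3%), 52.5% of PABPC1 reads (52.4% to 52.7%) and 74.1% of PABPC4 reads (74.0% to 74.2%). Mitochondrial rRNA went the other way, with 55.4% of IgG reads (55.2% to 55.6%), 38.3% of PABPC1 reads (38.2% to 38.5%) and 16.3% of PABPC4 reads (16.2% to 16.4%). Long non-coding RNA went with mRNA, at 1.80% in IgG, 2.53% with PABPC1 and 3.48% with PABPC4. The 7SL RNA of the signal recognition particle, with its copies, went with mitochondrial rRNA, at 0.732%, 0.307% and 0.160%. Messenger RNA encoded by the mitochondrial genome stayed between 3.41% (PABPC4) and 4.32% (PABPC1), with 3.47% in IgG. Outside mitochondrial rRNA, libraries of the same antibody differed by little more than sampling. Over genes with at least 20 summed reads, the chi-square per degree of freedom was 1.08 for IgG (828 genes), 1.07 for PABPC1 (3624 genes) and 1.17 for PABPC4 (8484 genes). It was larger over genes with at least 200 reads, at 2.16, 1.65 and 1.81. The share of mitochondrial rRNA did differ between the PABPC1 libraries, by more than the counting intervals above. Genes split by library held 169575 of 289217 reads in library A and 178141 of 277552 in library B. Most of the rest was mitochondrial rRNA.

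**Figure D1:**
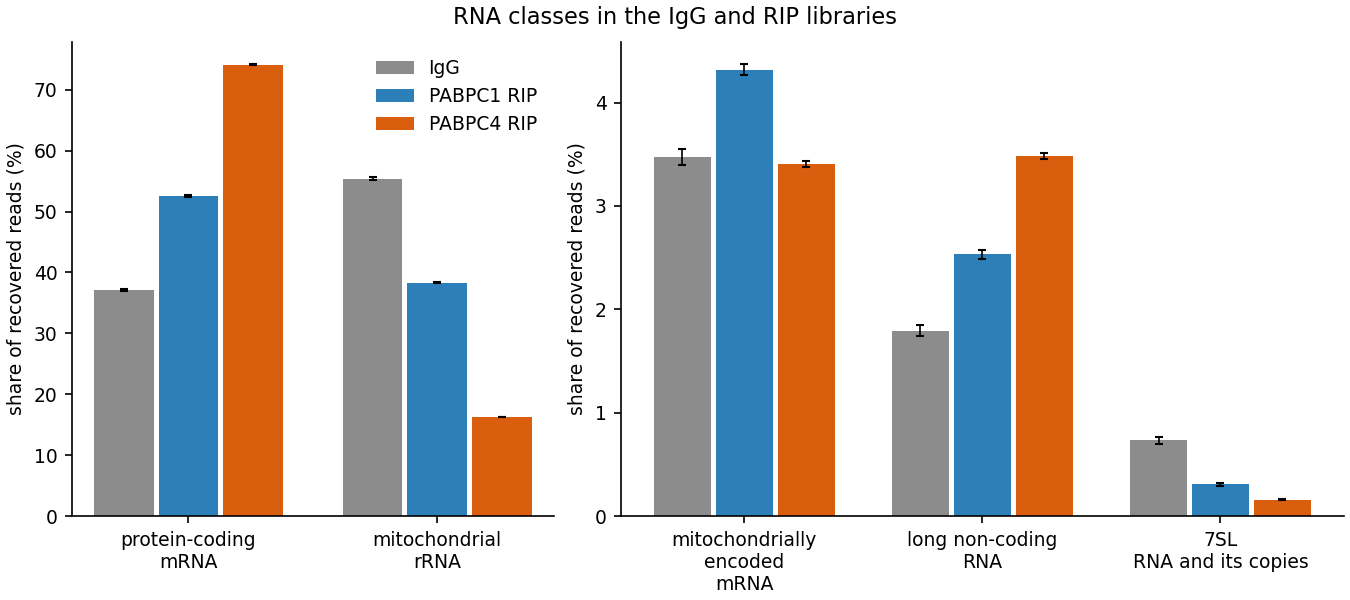
Share of reads (percent) in each RNA class for the IgG, PABPC1 RIP and PABPC4 RIP libraries, reads summed over the 2 libraries of each, with exact 95% intervals for counting error as error bars. Mitochondrial rRNA falls from 55.4% in IgG to 38.3% and 16.3% in the RIPs, and protein-coding mRNA rises from 37.1% to 52.5% and 74.1%.

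The comparison of PABPC1 with IgG gave 235 genes listed higher and 34 listed lower in the authors' deposited table, of 17565 with a p-value. Of the 235, 217 were protein-coding mRNAs and 11 were mRNAs encoded in mitochondria. In the authors' deposited table, CNBP, which encodes a zinc-finger nucleic-acid-binding protein, was 14.2-fold higher (443 RIP reads against 13, deposited adjusted p = 1.7e-30). The same deposited table, by the authors, listed KLF6, a zinc-finger transcription factor of the immediate early response, at 4.64-fold (adjusted p = 8.8e-10) and ATF4, the main transcription factor of the integrated stress response, at 2.94-fold (adjusted p = 2.9e-21). Haemoglobin mRNA was lower, with HBB at 0.346-fold in the authors' deposited table (434 reads against 503, adjusted p = 6.1e-61).

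The largest folds belonged to genes with few IgG reads. RAB11B-AS1, an antisense transcript of RAB11B, had 46 PABPC1 reads and 0 IgG reads, at least 6.15-fold higher. PPP2R5E, a regulatory subunit of protein phosphatase 2A, was at least 4.54-fold higher. RIDA, a deaminase of reactive imines abundant in liver, and SLC43A1, an amino acid transporter, were each at least 4.28-fold higher, with 32 reads against 0. The exact 95% lower limits of the 4 were 4.80, 3.50, 3.28 and 3.28. The authors' deposited table gave these 4 genes adjusted p-values of 0.00483, 0.0349, 0.0478 and 0.0478. It listed FKBP2, a prolyl isomerase of the endoplasmic reticulum, at 16.1-fold in the authors' deposited table (83 reads against 2, counting interval 4.46 to 139.7). SP100, a component of PML nuclear bodies, stood at 13.5-fold in the authors' deposited table (86 reads against 3, counting interval 3.80 to 56.8). LLPH was listed at 45.8-fold in the authors' deposited table (97 reads against 1, counting interval 6.82 to 1552), but 87 of its 97 reads came from library B, and the call was lost without that library (7.86-fold). On the low side, the authors' deposited table listed the collagens COL6A2 at 0.0935-fold and COL1A1 at 0.148-fold. It also listed TNFAIP2, induced by tumour necrosis factor, at 0.134-fold, and RGS2, a regulator of G-protein signalling, at 0.179-fold in the authors' deposited table. SNORD3A, the U3 small nucleolar RNA, stood at 0.183-fold and INHBE, a secreted TGF-beta family subunit made in liver, at 0.189-fold in the authors' deposited table. The mRNA of PABPC1 itself was 2.03-fold higher in the authors' deposited table (adjusted p = 1.4e-05). PABPC4 was listed at 2.26-fold (adjusted p = 0.303) and MYC at 1.12-fold (adjusted p = 1) in the authors' deposited table. Several calls were lost with a library left out: FKBP2 and PABPC1 without IgG library A (13.8-fold and 1.93-fold), COL1A1 without PABPC1 library B (0.196-fold) and INHBE without PABPC1 library B or IgG library A (0.207 and 0.187). TNFAIP2, RGS2 and SNORD3A were lost without PABPC1 library A (0.0744, 0.164 and 0.205), PABPC1 library B (0.214, 0.210 and 0.196) or IgG library B (0.235, 0.235 and 0.376). Other folds moved by over 1.5 times with their call kept: LLPH to 71.2 without PABPC1 library A and 22.8 without IgG library B, SP100 to 7.07 without PABPC1 library B and 6.73 without IgG library B, COL6A2 to 0.0482 without PABPC1 library A and SNORD3A to 0.121 without IgG library A.

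By gene list, 7 of 52 MYC targets were listed higher against IgG (7 adjusted over the list alone). They included PAICS, an enzyme of purine synthesis, at 3.34-fold, the nucleolar protein NPM1 at 1.96-fold and NCL, nucleolin, at 1.15-fold in the authors' deposited table. Of the cell cycle genes 4 of 47 were higher (5 adjusted over the list alone), among them MKI67, the Ki-67 proliferation antigen, at 2.46-fold and TOP2A, topoisomerase 2 alpha, at 2.69-fold in the authors' deposited table. Of secreted liver proteins 7 of 56 were higher and 1 lower (13 and 1 adjusted over the list alone), with APOB, the apolipoprotein of very low density lipoprotein, at 1.92-fold and ITIH3 at 3.24-fold in the authors' deposited table. Among poly(A)-binding proteins and their partners 5 of 37 were higher (6 adjusted over the list alone). Their largest was PABPN1, the nuclear poly(A)-binding protein, at 2.59-fold in the authors' deposited table. Of heat shock genes 4 of 17 were higher (5 adjusted over the list alone), such as HSP90AA1 at 1.76-fold and HSPA4 at 2.44-fold in the authors' deposited table. Translation factors had 4 of 38 higher (7 adjusted over the list alone), led by EIF3H at 2.57-fold in the authors' deposited table. The unfolded protein and integrated stress response had 3 of 29 higher (5 adjusted over the list alone), although its list median turned from 0.51 (log2) under library totals to -0.00 under totals over nuclear-encoded genes (nuclear totals). The ribosomal protein mRNAs had 9 of 79 higher (10 adjusted over the list alone), with RPL5 at 2.56-fold in the authors' deposited table. Their median turned from 0.33 (log2) under library totals to -0.06 under median-of-ratios scaling. Hepatocyte markers had 3 of 15 higher (4 adjusted over the list alone), with ALB, albumin, at 2.12-fold in the authors' deposited table, and their median was 0.42 (log2) under library totals and -0.10 under nuclear totals. Nuclear long non-coding RNAs had 4 of 12 higher (4 adjusted over the list alone), with KCNQ1OT1, an imprinted antisense RNA, at 2.12-fold in the authors' deposited table. The calls of PAICS and TOP2A were lost without IgG library A (2.85-fold and 1.91-fold), ITIH3 without IgG library B (2.43-fold), EIF3H without IgG library A or B (4.02 and 1.89) and HSPA4 without PABPC1 library B, IgG library A or IgG library B (2.46, 1.79 and 3.79). TOP2A kept its call without IgG library B, at over 4-fold. These counts take no account of read depth. By camera, MYC targets (adjusted p = 0.160), cell cycle genes (0.392), secreted liver proteins (0.160) and heat shock genes (0.403) did not stand apart from all other genes.

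Mitochondrially encoded mRNAs had 11 of 13 listed higher (13 adjusted over the list alone), MT-ND4 at 1.24-fold and MT-ATP8 at 2.62-fold in the authors' deposited table, but the list median turned from 0.40 (log2) under library totals to -0.11 under nuclear totals. Markers of blood cells and erythrocytes had 4 of 11 lower (5 adjusted over the list alone) and 0 higher. Besides HBB they were HBA1 at 0.362-fold, HBA2 at 0.294-fold and PTPRC, the leukocyte antigen CD45, at 0.199-fold in the authors' deposited table. Of RNA polymerase III and other small RNAs 3 of 22 were lower (4 adjusted over the list alone), RN7SL2 among them at 0.402-fold in the authors' deposited table. A single member was called in 4 lists whose medians lay above 0 under library totals and below 0 under nuclear totals: SCD for cholesterol synthesis (29 members), H1F0 for histone variants (11), KLF6 for immediate early and AU-rich mRNAs (40) and PSMD7 for the proteasome (31). The authors' deposited table listed SCD, stearoyl-CoA desaturase, at 2.05-fold, H1F0, a linker histone, at 2.12-fold and PSMD7 at 8.81-fold with 3 IgG reads (counting interval 2.80 to 42.6). The call of PSMD7 was lost without IgG library A (10.6-fold) or B (7.51-fold). None passed among 61 KRAB zinc finger genes, 74 nuclear genes of oxidative phosphorylation, 20 actin and housekeeping genes, 42 replication-dependent histones, 28 p53 targets, 20 snoRNA host genes and 20 glycolysis genes. The smallest p-values there belonged to ZNF121 (4.41-fold, adjusted p = 0.169), ENO1 (1.60-fold, 0.128) and B2M (0.584-fold, 0.135) in the authors' deposited table. The fibroblast list had 1 of 8 lower (COL1A1), and 0 of 2 endothelial, 7 lymphocyte, 4 neuronal and 2 other epithelial markers passed.

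Set against all other genes by camera (limma), 3 of 23 lists stood lower in PABPC1 than in IgG: blood markers (median log2 -1.85, adjusted p = 1.9e-19), actin and housekeeping genes (-0.41, adjusted p = 0.0049) and replication-dependent histones (-0.54, adjusted p = 0.0159). With an estimated correlation the adjusted p-values were 0.0542, 0.422 and 0.422, so 0 lists passed, and 1 had an unadjusted p under 0.05. Across scalings, filters and left-out libraries the adjusted p stayed at or below 9.1e-08 for blood markers, and reached 0.126 for actin and housekeeping genes and 0.782 for histones. Without PABPC1 library B only the blood marker call was left, and the histone call was also lost without IgG library B, PABPC4 library A or PABPC4 library B. The medians of nuclear oxidative phosphorylation genes (0.08), mitochondrial mRNAs (0.02) and p53 targets (0.04) were above 0 while their tests against the other genes pointed down. The balance of calls depended on the library totals: with the median gene scaled to 1 (median-of-ratios), the same chi-square test gave 36 genes higher and 52 lower, 40.9% higher in place of 87.4%. Without IgG library A the table's 235 and 34 became 49 and 25, without IgG library B 94 and 16, without PABPC1 library B 139 and 16, and without PABPC1 library A 272 and 16.

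The PABPC4 comparison gave 1188 genes listed higher and 193 lower in the authors' deposited table, of 21455 with a p-value. Of the 1188, 1164 were protein-coding mRNAs. The authors' deposited table listed MKI67 at 6.04-fold (5190 reads against 115, adjusted p = 3.2e-102), HSP90AA1, the inducible cytosolic HSP90, at 4.65-fold (adjusted p = 2.3e-93) and NCL at 3.16-fold (adjusted p = 1.7e-213). HSPA5, the endoplasmic reticulum chaperone BiP, was 5.30-fold higher (adjusted p = 3.4e-22) in the authors' deposited table. MYC mRNA was listed at 2.25-fold (374 reads against 22, adjusted p = 0.00373), PABPC4 at 2.93-fold (adjusted p = 0.00319) and PABPC1 at 2.10-fold (adjusted p = 9.5e-08) in the authors' deposited table. The MYC call was lost without IgG library A (2.08-fold) and the PABPC4 call without IgG library A or B (4.07-fold and 2.30-fold). HBB was lower, at 0.136-fold (adjusted p = 7.8e-299) in the authors' deposited table.

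The 8 largest folds all had 0 IgG reads and between 75 and 114 PABPC4 reads. They were CCDC59 (at least 5.11-fold higher), NIFK-AS1, antisense to the nucleolar protein gene NIFK, and XRCC2, of homologous recombination (both at least 4.48-fold), CCDC112 (4.39), TIGD1 (4.17), CENPU, of the centromere, and NUS1, of dolichol synthesis (both 3.76), and SLC43A1 (3.36), with exact 95% lower limits from 2.67 to 4.09. Their adjusted p-values lay between 0.00409 and 0.0436 in the authors' deposited table. Of the 193 lower genes, 26 had 0 PABPC4 reads, and the smallest folds of the others had 1 read each. FLI1, an ETS factor of blood and endothelial cells, stood at 0.0229-fold (1 read against 6, counting interval 0.000487 to 0.185) in the authors' deposited table. The Toll-like receptors TLR6 (0.0271-fold, counting interval 0.000568 to 0.240) and TLR8 (0.0302-fold, 0.000682 to 0.339) and the cytokine receptor CSF2RB (0.0289-fold, 0.000568 to 0.240) followed in the authors' deposited table. RCSD1 (0.0324-fold) and the pseudogene GVINP1 (0.0358-fold) had 1 read against 4 (counting interval 0.000682 to 0.339) in the authors' deposited table. With a library left out, the calls lost were CSF2RB (0.0557-fold without IgG library A), TLR8 (0.0675 without PABPC4 library A, 0.0786 without IgG library B), RCSD1 (0.0668 without PABPC4 library B, 0.0393 without IgG library B) and GVINP1 (0.0675 without PABPC4 library A, 0.0557 without IgG library A). Each of the 6 genes stood at 0 without the PABPC4 library that held its read, and FLI1, TLR6 and CSF2RB at 0.0446, 0.0540 and 0.0535 without the other one. TLR8 stood at 0.0186 without IgG library A. The chi-square test is approximate at such counts, and Fisher's exact test called 169 genes lower, all of them among the 191 deposited lower calls with recovered reads.

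By gene list, MYC targets had 18 of 53 listed higher (22 adjusted over the list alone), with NOP58, a box C/D snoRNP protein, at 6.22-fold and NPM1 at 2.62-fold in the authors' deposited table. Cell cycle genes had 8 of 47 (13 adjusted over the list alone), with CENPF, of the kinetochore, at 5.23-fold, TOP2A at 5.81-fold and KIF20A, a mitotic kinesin with 2 IgG reads, at 9.82-fold (counting interval 2.76 to 84.5) in the authors' deposited table. Secreted liver proteins had 24 of 57 higher and 2 lower (29 and 2 adjusted over the list alone). APOB stood at 2.62-fold, FN1, fibronectin, at 1.74-fold and SPP1, osteopontin, at 7.43-fold in the authors' deposited table. SERPING1, the C1 inhibitor, had 0 PABPC4 reads against 3, at most 0.134-fold against the floor of 3 reads, with an exact 95% upper limit of 0.325. Translation factors had 15 of 38 (23 adjusted over the list alone), with EIF3A at 3.05-fold, EIF5B at 3.89-fold and BTF3 at 3.92-fold in the authors' deposited table. Poly(A)-binding proteins and partners had 13 of 36 higher (16 and 1 lower adjusted over the list alone), led by TNRC6A, a scaffold of microRNA silencing, at 4.24-fold in the authors' deposited table. Heat shock genes had 9 of 17 (11 adjusted over the list alone), including HSP90AB1 at 2.23-fold and HSPA4L, with 3 IgG reads, at 5.92-fold (counting interval 1.93 to 28.4) in the authors' deposited table. KRAB zinc finger genes had 4 of 67 (4 adjusted over the list alone), with ZNF91 at 3.79-fold and ZNF37A at 6.57-fold in the authors' deposited table. Without IgG library A or B the calls were lost of KIF20A (8.41-fold and 11.9-fold), BTF3 (8.91 and 2.52), HSPA4L (7.19 and 5.07) and ZNF37A (10.3 and 4.85), and that of SPP1 without IgG library B (3.72).

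Other lists turned direction when library totals were replaced, so their counts hold for the authors' scaling. The ribosomal protein mRNAs had 25 of 79 listed higher (29 and 1 lower adjusted over the list alone), with RPL22 at 3.47-fold in the authors' deposited table, and their median went from 0.63 (log2) to -0.20 under median-of-ratios. The stress response list had 9 of 30 (12 adjusted over the list alone), with HSP90B1, the endoplasmic reticulum HSP90, at 3.78-fold in the authors' deposited table, and a median of 0.85 (log2) that became -0.15 under nuclear totals. Hepatocyte markers had 8 of 15 (8 adjusted over the list alone; 0.82 to -0.01 under median-of-ratios), immediate early and AU-rich mRNAs 7 of 40 (8 adjusted over the list alone; 0.61 to -0.21) and nuclear long non-coding RNAs 4 of 13 (5 adjusted over the list alone; 0.99 to -0.01 under nuclear totals). The last 2 groups included JUN at 4.25-fold, DUSP6, with 3 IgG reads, at 4.89-fold (counting interval 1.78 to 26.2) and TUG1, also with 3, at 4.85-fold (counting interval 1.96 to 28.8) in the authors' deposited table. Glycolysis genes had 3 of 22 (3 and 1 lower adjusted over the list alone; 0.60 to -0.24), with ENO1, enolase, at 2.15-fold in the authors' deposited table. Proteasome genes had 3 of 31 (6 adjusted over the list alone; 0.96 to -0.04 under nuclear totals), with PSMD7 at 6.27-fold against 3 IgG reads (counting interval 2.04 to 29.9) in the authors' deposited table. Actin and housekeeping genes had 2 of 20 higher and 1 lower (2 and 1 adjusted over the list alone; 0.24 to -0.58), with B2M, of MHC class I, at 0.285-fold in the authors' deposited table. Counts of 2 were found for replication-dependent histones (2 of 49), p53 targets (2 of 28), cholesterol synthesis (2 of 29) and nuclear oxidative phosphorylation (2 of 75, 1 adjusted over the list alone). They included HIST1H1C at 2.06-fold, GADD45A at 3.70-fold, SCD at 1.88-fold and ATP5C1 at 4.24-fold in the authors' deposited table; SCD stood at 0.951-fold under nuclear totals. Without IgG library A the calls were lost of HIST1H1C (1.80-fold), TUG1 (2.43) and GADD45A (2.37), which stood at 8.38 without IgG library B. Those of ATP5C1 (8.13 and 2.87), PSMD7 (7.58 and 5.35) and DUSP6 (3.31 and 9.36) were lost without IgG library A or B, and DUSP6 also without PABPC4 library B (4.90). Histone variants had 1 of 11 (H1F0, 2.36-fold in the authors' deposited table), and 0 of 21 snoRNA host genes passed.

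Mitochondrially encoded mRNAs split, with 1 of 13 listed higher and 2 lower (3 and 2 adjusted over the list alone). MT-ATP8 stood at 1.79-fold, MT-ND4 at 0.869-fold and MT-ND6 at 0.829-fold in the authors' deposited table; MT-ATP8 became 0.989-fold under median-of-ratios. Blood markers had 6 of 10 lower (6 adjusted over the list alone) and 0 higher, with HBA1 at 0.189-fold, HBA2 at 0.128-fold and S100A8, a calcium-binding protein of neutrophils, at 0.0968-fold in the authors' deposited table. Small RNAs had 5 of 23 lower (6 adjusted over the list alone), with RN7SL2 at 0.209-fold and SNORD3A at 0.0769-fold in the authors' deposited table. Fibroblast markers had 3 of 9 lower (4 adjusted over the list alone), with COL1A1 at 0.0664-fold and COL1A2 at 0.205-fold in the authors' deposited table. POSTN, the other one, and GNLY, 1 of 9 lymphocyte markers (2 adjusted over the list alone), each had 1 read against 3 (counting interval 0.000853 to 0.558) and were not called by Fisher's exact test (adjusted p = 0.0692). PECAM1, 1 of 4 endothelial markers, was at 0.334-fold in the authors' deposited table. Its call was lost without PABPC4 library B (0.340-fold) or IgG library A (0.483), and that of MT-ATP8 without PABPC4 library B (1.58), IgG library A (2.04) or IgG library B (1.60). The POSTN call was lost without any 1 of the 4 libraries (0 to 0.0891) and the GNLY call without PABPC4 library A (0.0900) or B (0). With their calls kept, GNLY moved to 0.0262 without IgG library B and S100A8 to 0.0427 without PABPC4 library A. None of 6 neuronal or 2 other epithelial markers passed over all genes, and 1 of the latter did adjusted over the list alone.

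Against all other genes, camera (limma) put 4 of 23 lists apart in PABPC4: blood markers lower (median log2 -3.71, adjusted p = 4.7e-32), mitochondrial mRNAs lower (-0.73, adjusted p = 1.4e-30; 0.09 under library totals), actin and housekeeping genes lower (-0.58, adjusted p = 5.8e-05; 0.24 under library totals) and heat shock genes higher (0.42, adjusted p = 0.011; above 0 under all 3 scalings). With an estimated correlation the adjusted p-values were 0.0256, 0.263, 0.263 and 0.276. Over the other settings the highest adjusted p was 2.9e-14, 0.011, 0.0321 and 0.0457 in the same order. MYC targets (0.38), secreted liver proteins (0.41) and ribosomal protein mRNAs (-0.20) missed the threshold, each with an adjusted p of 0.052, and so did cell cycle genes (0.36, adjusted p = 0.0909). Median and test differed in sign for oxidative phosphorylation (0.04, test down), cholesterol synthesis (0.08, down), proteasome (0.13, down) and hepatocyte genes (-0.01, up). As for PABPC1, the balance of calls depended on the totals: median-of-ratios gave 170 higher and 398 lower, 29.9% higher in place of 86.0%, and MYC, PABPC4 and PABPC1 were then no longer called. Without IgG library A the 1188 and 193 became 408 and 107, without IgG library B 705 and 99, without PABPC4 library A 1201 and 116, and without PABPC4 library B 1248 and 112.

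**Figure D2:**
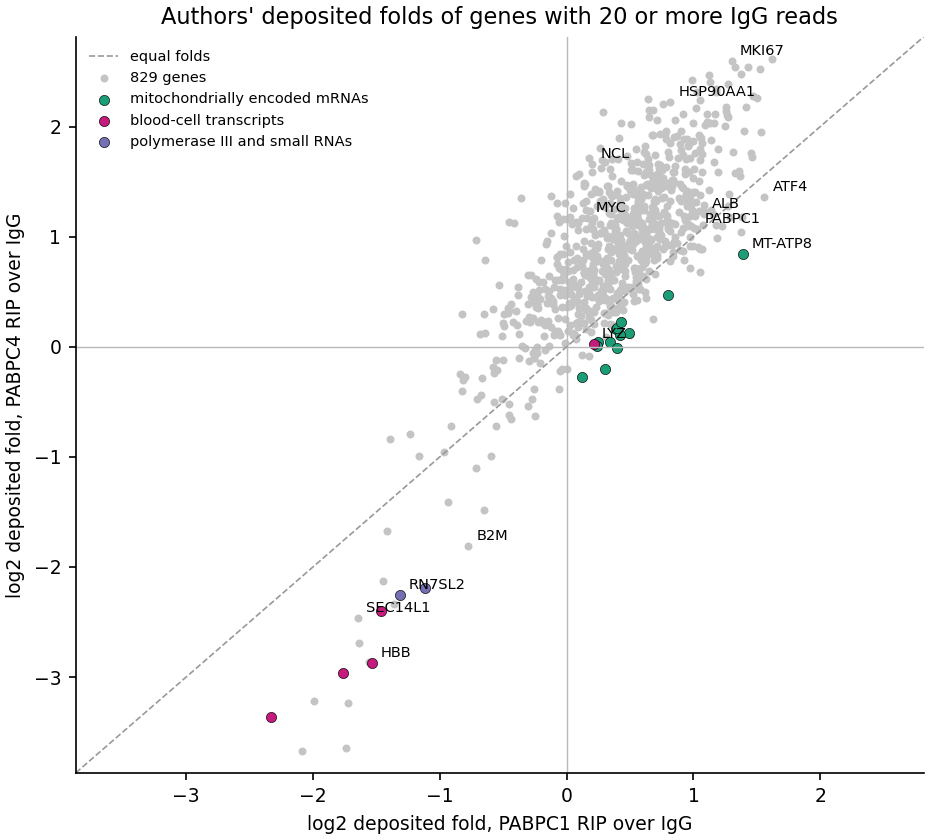
Deposited fold over IgG (log2) with PABPC1 (horizontal) and PABPC4 (vertical) for genes with at least 20 IgG reads, with mitochondrial mRNAs, blood-cell transcripts and small RNAs coloured, some genes named and equal folds as a dashed line. The medians of the 829 genes lie at 0.41 and 0.94, HBB, SEC14L1 and RN7SL2 lie below 0 on both axes, and in limma with median-of-ratios scaling the medians of all genes are 0.06 and 0.07.

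The lists of the proteins overlapped. Of the 235 genes higher with PABPC1, 209 were also higher with PABPC4, among them CNBP, ATF4, KLF6, APOB and MKI67, where independent lists would share 17.01 of 16413 genes (two-sided Fisher's exact test across genes, p = 3.2e-213). Of the 34 lower with PABPC1, 30 were lower with PABPC4, HBB and COL1A1 included (0.400 for independent lists, Fisher's exact test, p = 5.5e-55). Both comparisons used the same IgG reads. Unchanged groups simulated against those reads shared 0 genes in either direction in 100 simulations, but these made at most 0 higher and 4 lower calls, so they give no expected overlap. Taking a separate IgG library for each protein, 65 of 94 higher calls with PABPC1 were shared (2.34 for independent lists) or 40 of 49 (2.10). Which of these applied depended on which library went with which protein. Part of the excess may come from the shared controls. Genes with few reads could hardly be called higher with either protein: the called genes had medians of 176 (PABPC1) and 343 (PABPC4) RIP reads. The values for independent lists leave out such shared read depth, so part of the excess may also come from it. Under median-of-ratios scaling 18 of 36 higher calls with PABPC1 were shared (0.373 for independent lists) and 50 of 52 lower calls (1.26).

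The difference between the enrichments asks which RNAs were enriched more with PABPC4 than with PABPC1. For NCL the authors' deposited table listed 3.16-fold with PABPC4 and 1.15-fold with PABPC1. For HSP90AA1 the folds were 4.65 and 1.76, and for MKI67 6.04 and 2.46, in the authors' deposited table. The reverse held for KLF6, at 3.57 with PABPC4 and 4.64 with PABPC1, and for MT-ATP8, at 1.79 and 2.62, in the authors' deposited table. Over 3624 genes with at least 20 PABPC1 reads the median log2 ratio of the folds was 0.39 (SD across genes 0.474), and 81.6% of genes lay above 0. This shift of the median gene held only on library totals: it was -0.06 under median-of-ratios, -0.05 without mitochondrial rRNA and -0.10 under nuclear totals. Median-of-ratios places the median gene near 0 by construction, and the other totals leave out mitochondrial rRNA. These values therefore cannot tell scaling from a wider enrichment of mRNA with PABPC4.

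Compared directly and relative to the median gene, the mRNAs of NCL, HSP90AA1, MYH9 and MYH10 were higher in the PABPC4 RIP than in the PABPC1 RIP, and HBB, MT-ND4 and NEAT1 were lower. NCL was 1.02 higher on the log2 scale (SE 0.052, limma adjusted p = 3.3e-18) and HSP90AA1 0.96 higher (SE 0.0934, adjusted p = 6.3e-10). The non-muscle myosin heavy chains MYH9 and MYH10 were 1.26 and 1.41 higher (adjusted p = 1.1e-08 and 4.8e-06). In the other direction HBB fell by 1.79 (SE 0.119, adjusted p = 1.0e-14), MT-ND4 fell by 0.96 (SE 0.0513, adjusted p = 1.5e-17) and the paraspeckle RNA NEAT1 fell by 0.66 (SE 0.0308, adjusted p = 3.0e-19). In all, limma called 188 genes higher and 166 lower of 7976 (683 and 624 at an unadjusted p under 0.05).

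The largest fold belonged to KRI1, of ribosome biogenesis, at 2.68 (log2, SE 0.550, adjusted p = 0.00153), with 172 PABPC4 reads against 8. The next 7 had 1 or 2 PABPC1 reads, so that their fitted folds depend on the prior count. Their count ratios were 6.29 for ZNF330 (counting interval 1.65 to 53.3), 9.61 for the SNARE gene USE1 (1.63 to 389.3), 5.67 for CHAMP1, of chromosome alignment (1.48 to 48.2), and 8.38 for SRGAP2D, a copy of SRGAP2 (1.41 to 340.7). They were 8.13 for the transcription factor GATA2 and for ZNF354A (1.36 to 330.9) and 5.05 for SMG8, of nonsense-mediated decay (1.31 to 43.1). The largest decreases were S100A8 (-2.63), the lysosomal trafficking regulator LYST (-2.63), collagen COL6A3 (-2.41), the leukocyte plastin LCP1 (-2.33), the liver alcohol dehydrogenase ADH4 (-2.19) and moesin, MSN (-2.17), with adjusted p-values from 5.4e-07 to 0.00755. S100A8, LYST, LCP1 and MSN had 14 and 5, 6 and 10, 6 and 18, and 13 and 12 reads in IgG libraries A and B. Their PABPC1 reads were 18, 17, 20 and 15 and their PABPC4 reads 13, 11, 16 and 15. Relative to library totals, these genes were thus highest in IgG and lower in both RIPs. COL6A3 (1 and 3 IgG reads) and ADH4 (2 and 0) were not. MYC was 0.57 higher without passing the test (SE 0.214, adjusted p = 0.132). PABPC1 mRNA fell by 0.40 (adjusted p = 0.0209) and PABPC4 mRNA stood at -0.06 (adjusted p = 0.924), so its overexpression, given in the labels, was not seen in the RIP reads. These directions depend on the scaling: on library totals the folds over IgG were 2.10 with PABPC4 and 2.03 with PABPC1 for PABPC1 mRNA, and 2.93 and 2.26 for PABPC4 mRNA, in the authors' deposited table.

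**Figure D3:**
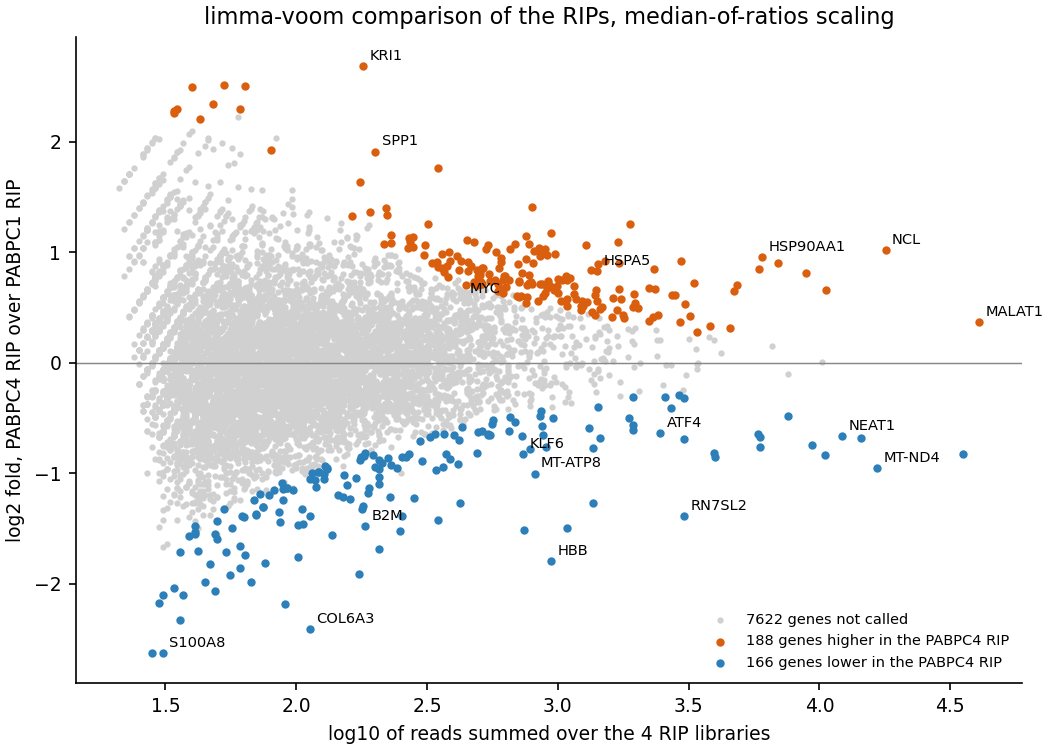
Log2 fold of PABPC4 RIP over PABPC1 RIP (limma-voom, median-of-ratios scaling) against the reads summed over the 4 RIP libraries (log10), 1 point per gene for 7976 genes, with called genes coloured. The 188 higher and 166 lower calls include NCL at 1.02 and HBB at -1.79.

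Among the lists, mitochondrially encoded mRNAs had 13 of 13 lower (13 adjusted over the list alone), with a median of -0.76, and camera gave an adjusted p of 1.6e-59 (0.154 with an estimated correlation). The lowest was MT-ATP8, at 0.499-fold. Blood markers had 5 of 7 lower (7 adjusted over the list alone), with a median of -1.69 and an adjusted p of 2.5e-14 (0.0878 with an estimated correlation). Heat shock genes had 1 of 16 higher, HSP90AA1 (3 adjusted over the list alone), with a median of 0.22 and an adjusted p of 0.00884 (0.307 with an estimated correlation), and this call was lost without PABPC1 library A or B (highest adjusted p = 0.0788). Glycolysis had 0 of 15 called (0 adjusted over the list alone; PGK1 had the smallest p, log2 -0.80, adjusted p = 0.118), with a median of -0.31 that turned to 0.12 under library totals and an adjusted p of 0.0435 (0.307 with an estimated correlation, up to 0.625 over other settings), and this call was lost without PABPC1 library A, PABPC4 library A or PABPC4 library B. Across settings the adjusted p stayed at or below 5.9e-25 for mitochondrial mRNAs and 2.1e-06 for blood markers. With an estimated correlation 0 lists passed, and 2 had an unadjusted p under 0.05.

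Single members moved in lists whose test did not pass. Of 42 cell cycle genes 5 were higher (5, and 2 lower, adjusted over the list alone), with BUB1B, of the spindle checkpoint, at 0.86. MYC targets split, with 3 of 44 higher and 3 lower (5 and 3 adjusted over the list alone), from NCL to TFRC, the transferrin receptor (-0.95). Translation factors split too, with 3 of 37 higher and 2 lower (7 and 5 adjusted over the list alone), EIF3B at 0.83 and EEF1A1 at -0.50. In the stress response list 3 of 27 were higher and 1 lower (3 and 1 adjusted over the list alone), HSPA5 at 0.83 and ATF4 at -0.64. Secreted liver proteins had 3 of 40 higher and 1 lower (6 and 1 adjusted over the list alone), SPP1 at 1.91 and ALB at -0.32 (but 2.31-fold over IgG with PABPC4 and 2.12-fold with PABPC1 in the authors' deposited table, on library totals). Poly(A)-binding proteins and partners had 3 of 35 lower (5 adjusted over the list alone; list median -0.07, but 0.36 under library totals), with PABPN1 at -0.77. Of nuclear long non-coding RNAs MALAT1 rose by 0.37 and NEAT1 fell. B2M fell by 1.48 in the housekeeping list, RN7SL3 fell by 1.51 with 2 of 2 small RNAs, KLF6 fell by 0.82, RPS2 by 0.76, SCD by 0.57 and SNHG3 by 0.82, and UQCRB rose by 0.87. H1F0 fell by 0.29 relative to the median gene, while its folds over IgG were 2.36 with PABPC4 and 2.12 with PABPC1 in the authors' deposited table. PSMB2, of the proteasome, stood at 0.355-fold. None passed among 35 KRAB zinc finger genes (ZNF83 0.96, adjusted p = 0.121), 23 p53 targets (TP53INP1 -0.91, adjusted p = 0.119) and 24 replication-dependent histones (HIST1H3H -1.11, adjusted p = 0.157). Median, mean and test differed in sign for translation factors (median -0.06, mean 0.02, test up), histone variants (0.25, 0.06, test down) and snoRNA host genes (0.02, 0.01, test down).

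The number of calls in this comparison depended on the PABPC1 libraries and the scaling, and a lost call does not show that a fold changed. Without PABPC1 library A limma called 7 genes higher and 10 lower, without PABPC1 library B 2 and 12, and without PABPC4 library B 360 and 298, so that most calls named for this comparison were lost with either PABPC1 library left out. Library totals gave 1108 and 55, with the median gene at 0.45.

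**Figure D4:**
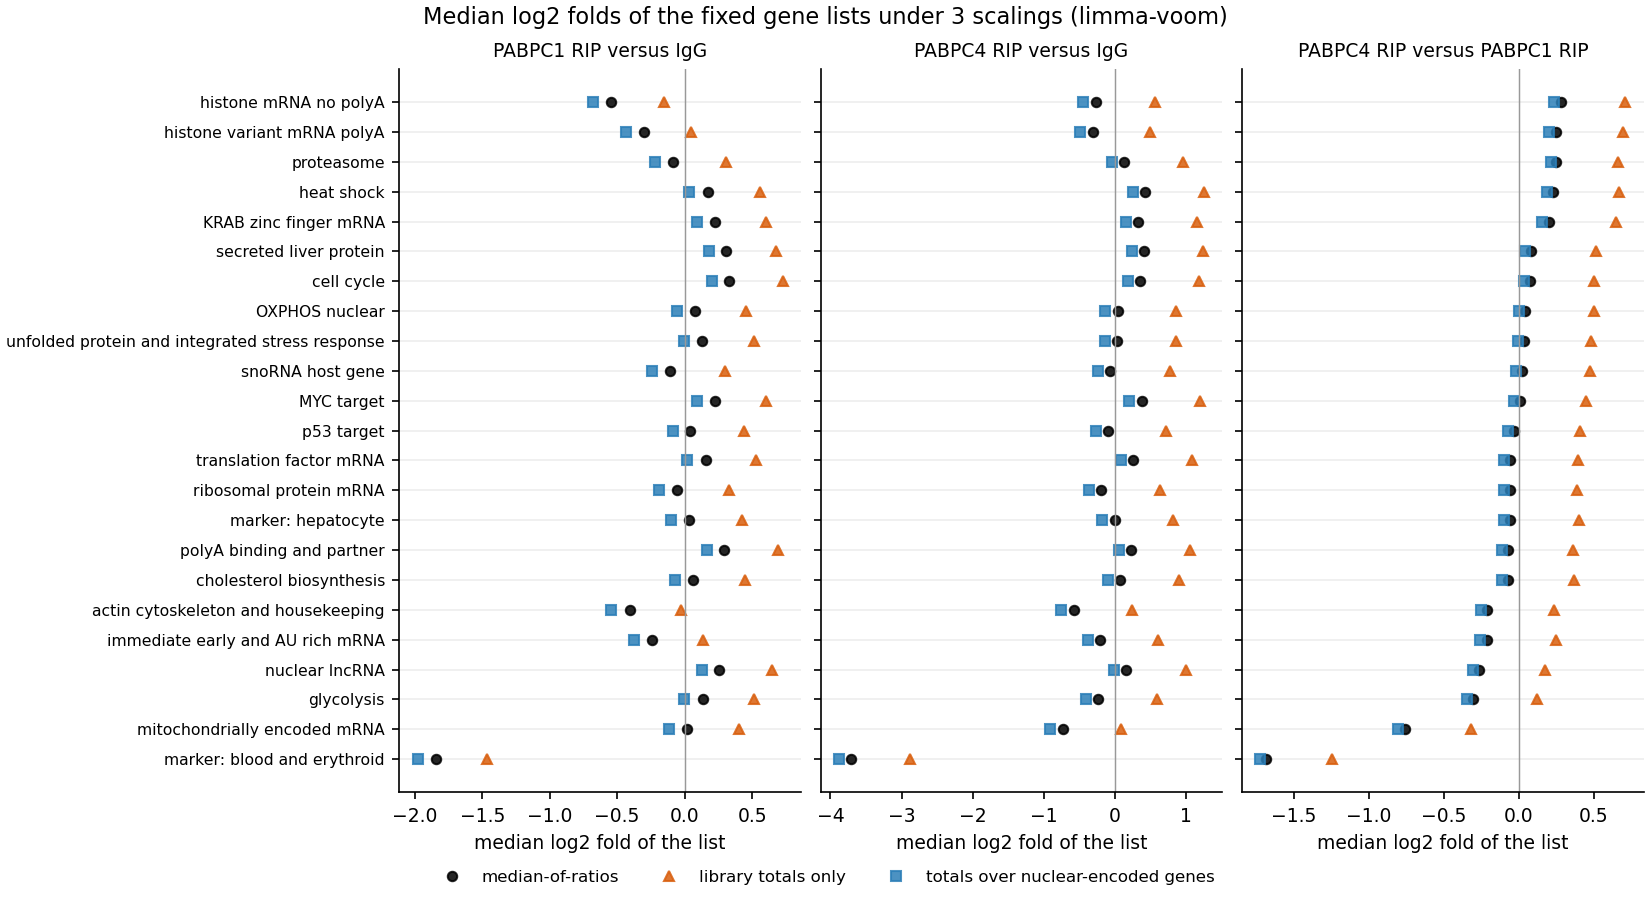
Median log2 fold of each gene list with at least 5 tested genes (rows) in the 3 limma comparisons (panels), under median-of-ratios scaling (circles), library totals (triangles) and totals over nuclear-encoded genes (squares). Blood markers lie below 0 in every panel and scaling, mitochondrial mRNAs lie below 0 in the right panel under all 3, and many other lists change side with the scaling.

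The IgG libraries were compared as a description, since each came from a different cell population and neither is replicated. Over 828 genes with at least 20 IgG reads the log2 ratio of library A to library B had a median of -0.08 and an SD of 0.552. Counting error alone was exceeded by 2 genes (exact binomial test, adjusted p under 0.05), SEC14L1 with 304 and 312 reads and IGF2 with 1652 and 1383, which does not show a difference between the cell populations. The overexpressed genes gave no basis for assigning these libraries to a cell population, with 38 and 30 reads of PABPC1 (chromosome 8, 100702916 to 100722088, GRCh38) and 10 and 4 reads of PABPC4 (chromosome 1, 39560816 to 39576790). MYC (chromosome 8, 127735434 to 127742951) had 12 and 10 IgG reads, 25 and 37 PABPC1 reads, and 194 and 180 PABPC4 reads.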

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

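The limma comparison of the RIPs and the tests of explanations in this part were chosen after the results were seen, while list tests with library totals, an estimated correlation or a library left out were planned. The PABPC4 and PABPC1 RIPs differed by that test in 188 genes higher and 166 lower with PABPC4, where NCL rose by 1.02 (log2) and HBB fell by 1.79. Without PABPC1 library A the counts were 7 and 10, without PABPC1 library B 2 and 12, and without PABPC4 library B 360 and 298. At the level of gene lists, mitochondrial mRNAs (median log2 -0.76), blood markers (-1.69) and glycolysis (-0.31) were lower with PABPC4 and heat shock genes higher (0.22). With an estimated correlation none of these 4 calls passed (adjusted p = 0.154, 0.0878, 0.307 and 0.307), and 0 of 15 glycolysis genes were called. The glycolysis median was 0.12 under library totals, and its call was lost without PABPC1 library A, PABPC4 library A or PABPC4 library B (adjusted p up to 0.625). The heat shock call was lost without PABPC1 library A or B (up to 0.0788). Antibody, protein and overexpressing cell population differ together between the RIPs, so no test here separates them.

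Blood-cell RNA in HepG2 libraries was the least anticipated of these. Blood markers made up 3646 and 3725 CPM in the IgG libraries, 1297 and 1427 with PABPC1 and 723 and 566 with PABPC4, with HBB at 293 and 210 reads in IgG. Scaling of the libraries is argued against as the cause, since the highest of the list's medians of PABPC4 over IgG under 3 scalings was -2.88. A single odd IgG library is argued against as well, with the lower IgG library 2.56 times the highest RIP library. A foreign RNA present in a fixed mixture in every library would lower all members alike. The 7 members with enough reads were not lowered alike, with a heterogeneity chi-square of 23.4 per degree of freedom (chi-square test, p = 8.9e-28) against 5.51 between the PABPC4 libraries. This p covers counting error only. LYZ, lysozyme, held the difference, at 1.02-fold in the authors' deposited table while HBB stood at 0.136. Whether the LYZ reads had the same source as the others was not tested, so the value of 23.4 does not exclude a foreign mixture. For the members other than LYZ the value was 2.19 (chi-square test, p = 0.0529) against 4.31 between the PABPC4 libraries. For these 6, blood RNA carried into all libraries and diluted where a RIP yielded more RNA cannot be told apart from a difference in binding. The value of 2.19 lay between the limits set for and against a fixed mixture, so it decides nothing. The scatter between the PABPC4 libraries was larger still, and no biological explanation was tested. The fall was not limited to blood markers, whose summed reads stood at 0.370 (PABPC1) and 0.175 (PABPC4) of IgG on library totals. Fibroblast markers stood at 0.340 and 0.118, endothelial at 0.401 and 0.336, lymphocyte at 0.583 and 0.537, and small RNAs at 0.419 and 0.213. Neuronal and other epithelial markers went the other way, at 2.27 and 2.17 with PABPC1 and higher with PABPC4. These other marker lists held at most 33 IgG reads each. A source shared by the lower lists was not tested.

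Mitochondrial mRNAs were lower with PABPC4 in 13 of 13 genes, with a median log2 fold of -0.76 and the highest at -0.64. Scaling is argued against as the cause: the highest of the medians under 3 scalings was -0.32, and the highest single member lay at -0.20. Carry-over of 1 pool of mitochondrial RNA, rRNA and mRNA together, would lower both alike, but the lowest mRNA lay 0.67 above the mitochondrial rRNA (-1.68). That value argues against a pool of fixed composition as the whole cause and leaves a part of it open. The rRNA value is a remainder of the totals without an error, and the rRNA share differed between the PABPC1 libraries. A pool whose share of rRNA varied between libraries is therefore not excluded. A lower affinity of PABPC4 than PABPC1 for the short tails of mitochondrial mRNA could also give the pattern and was not tested.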

How the results depend on the processing

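Alternatives chosen after the data were seen are the chi-square tests with other totals, the 2-fold threshold on the deposited calls (planned for the overlap), Fisher's exact test, limma, the thinning, the separate IgG libraries, the minimum of 50 PABPC1 reads, the list tests with nuclear totals and all gene counts of the PABPC4 to PABPC1 comparison. Where a value below moved, the cause was not tested unless stated. No paired analysis was possible because the recovered libraries carry no replicate number.

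With PABPC1 against IgG (235 higher, 34 lower), an adjusted p under 0.01 gave 136 and 20, over 2-fold 147 and 30, and at least 20 reads in 2 libraries 334 and 21. Totals without mitochondrial rRNA gave 29 and 76 (27.6% higher), nuclear totals 24 and 71 (25.3%) and median-of-ratios 36 and 52. Limma gave 44 and 33 with median-of-ratios (610 and 413 at an unadjusted p under 0.05) and 370 and 29 with library totals. Fisher's exact test gave 310 and 34. Leaving out each library gave 49 (without IgG library A) to 272 (without PABPC1 library A) higher and 16 to 25 lower.

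With PABPC4 against IgG (1188 higher, 193 lower), the same settings gave 860 and 149, 1079 and 188, and 1748 and 26. Totals without mitochondrial rRNA gave 131 and 425 (23.6% higher), nuclear totals 110 and 436 (20.1%) and median-of-ratios 170 and 398. Limma gave 196 and 131, or 2290 and 51 with library totals, and Fisher's exact test 1560 and 169. Leaving out each library gave 408 (without IgG library A) to 1248 (without PABPC4 library B) higher and 99 to 116 lower. Thinned to 566769 reads, the PABPC1 depth, PABPC4 gave 1139 higher (1093 to 1174 over 100 draws) and 87 lower, or 146 and 203.5 with median-of-ratios.

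The median difference between the enrichments (0.39) was -0.05, -0.10 and -0.06 under the 3 other totals, 0.46 with at least 50 PABPC1 reads and 0.33 to 0.49 with a library left out. PABPC4 against PABPC1 (188 higher, 166 lower) gave 0 and 2 when tested against a log2 fold of 1 with limma's treat (15 and 31 at an unadjusted p under 0.05), 94 and 91 at an adjusted p under 0.01, 1108 and 55 with library totals, 165 and 197 with nuclear totals, 124 and 148 without a filter, 219 and 178 with at least 20 reads. Leaving out each library gave 2 to 360 and 10 to 298, lowest without a PABPC1 library. The overlap of 209 became 127 (over 2-fold), 12 (without mitochondrial rRNA), 8 (nuclear totals), 18 (median-of-ratios), 65 (PABPC1 against IgG library A, PABPC4 against B) and 40 (the reverse).

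Lists called by camera (3, 4 and 4 for the comparisons in that order) became 0, 1 and 0 with an estimated correlation, 10, 10 and 8 with library totals and 3, 5 and 5 with nuclear totals. Leaving out each library gave 1 (without PABPC1 library B) to 4, 4 to 6, and 2 (without PABPC1 library A) to 4. Among 79 values of named genes, median-of-ratios left 52 on their side of the threshold, moved 25 out and 1 in, and reversed 1. Without mitochondrial rRNA these were 50, 27, 1 and 1, and with nuclear totals, which give a value for 74 of them, 46, 26, 1 and 1. Leaving out libraries kept 224 of their values, ended 66 and added 2. The reversed folds were MT-ATP8 with PABPC4, at 0.934 without mitochondrial rRNA and 0.989 with median-of-ratios, and SCD with PABPC4, at 0.951 with nuclear totals.

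Not run were edgeR (TMM and RLE factors, glmTreat), DESeq2 and another pseudocount. The replicate number as a block was not run either, since the recovered libraries carry no names. Both ways of giving each protein a separate IgG library were run for the overlap, but which of them follows the cell populations is unknown. The pooled IgG, library totals and no filter are what the deposited tables already use. The IgG depth of 227265 reads limits both comparisons with IgG.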

Other observations

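The tests of this part were chosen after the results were seen, except the comparison of charged nuclear with multi-pass membrane proteins, which was written down before its values were looked at. Among the genes higher in the PABPC4 RIP than in the PABPC1 RIP were mRNAs of coiled-coil proteins. They included the myosin heavy chains MYH9 (log2 1.26, limma adjusted p = 1.1e-08) and MYH10 (1.41, 4.8e-06) and the cohesin subunits SMC1A (1.09, 3.5e-07) and SMC3 (0.78, 0.00164). KIF5B, a kinesin heavy chain, was 0.51 higher (adjusted p = 0.00214) and GOLGA4, a golgin, 0.36 higher (0.00964). DSP, desmoplakin of desmosomes (0.90), CALD1, the actin-binding caldesmon (0.84), and RRBP1, the ribosome-binding protein of the endoplasmic reticulum (0.65), were higher too; these 3 lie outside the tested families and were chosen after their values were seen. Genes lower with PABPC4 included the taurine transporter SLC6A6 (-1.13, adjusted p = 0.00252) and the membrane proteins TMEM123 (-0.53, 0.0251) and TSPAN3 (-1.32, 0.00113).

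Taken by family names, 102 coiled-coil genes had a median log2 of 0.34 with 80 above 0 (camera, unadjusted p = 1.1e-07; 0.0431 with an estimated correlation), and it was 0.78 under library totals. Of the 188 genes called higher, 8 were among them, and 0 of these genes were called without PABPC1 library A or B. The median was then 0.39 and 0.30 (camera, unadjusted p = 2.7e-06 and 2.8e-05; 0.133 and 0.148 with an estimated correlation). Genes named SLC or TMEM (176) had a median of -0.20 with 64 above 0 (camera, unadjusted p = 0.00706; 0.0608 with an estimated correlation), which turned to 0.25 under library totals, and their p was 0.155 without PABPC1 library A, 0.00115 without PABPC1 library B and 0.457 without a filter (0.144, 0.0381 and 0.509 with an estimated correlation). Both groups were picked after they were seen to move, so their p-values restate that choice. Genes called higher were longer (median 7109.5 nucleotides) than genes called lower (4130.5), a ratio of 1.72, although length and fold were nearly unrelated over all genes (Spearman rho 0.0142). Gene length, as implied by the deposited folds, is still argued against as the cause of this split. The coiled-coil and the SLC and TMEM genes were alike in it (ratio of medians 1.01, bootstrap 95% interval 0.798 to 1.19). The lengths of the expressed transcripts and of their coding sequences were not known. Translation at the endoplasmic reticulum stays open for this split. The mRNAs of secreted liver proteins lay 0.28 above the SLC and TMEM genes (permutation test across genes, p = 0.00442) but 0.26 below the coiled-coil genes. At a median of 0.08 they did not share the fall of the SLC and TMEM genes. The permutation p treats genes as independent and does not measure the spread between libraries.

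A wider split was then tested on families not used to see the pattern. Splicing and chromatin families of charged nuclear proteins (106 genes, median 0.27, 82 above 0) lay 0.29 above multi-pass membrane families (55 genes, median -0.02, 26 above 0). Permuting genes between the families gave p = 1e-05 (permutation test), the smallest these permutations can give. This p treats genes as independent and does not measure the spread between libraries. PRPF4B, a kinase of the spliceosome (1.03, limma adjusted p = 0.000121), ZC3H13, of the m6A writer complex (adjusted p = 3.5e-06), and PRPF6, of the spliceosome (0.75, 0.00992), were among the 6 called higher. The charged families also lay above all other genes (camera, unadjusted p = 6.9e-06; 0.0644 with an estimated correlation), while the membrane families did not lie apart from them (p = 0.547). Without PABPC1 library A or B, 0 charged genes were called, with medians of 0.19 and 0.28 against 0.04 and -0.07 for the membrane families, so without library A the split was narrower (camera for the charged genes, unadjusted p = 0.000555 and 0.000107; 0.198 and 0.142 with an estimated correlation). The membrane families were picked by symbol and include ABCF1, without membrane spans, which was 0.75 higher. No mechanism was tested, and a difference between the antibodies or the cell populations stays open.

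Some abundant RNAs moved apart from their surroundings. IGF2, an imprinted growth factor, had 10813 PABPC1 reads and fell by 0.82 (log2) with PABPC4 (limma adjusted p = 6.2e-23). SEC14L1 stood at 0.319-fold with PABPC1 and 0.181-fold with PABPC4 in the authors' deposited table. In the IgG libraries it held 304 and 312 reads.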
